A study of Candida albicans with 96 samples.

How the data were processed

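The series measured RNA of biofilm and planktonic Candida albicans cells at 6, 12 and 48 h on 96 arrays with 2 dyes. Per the labels, total RNA was taken with hot phenol and a column kit, turned into aminoallyl cDNA and coupled to Cy3 or Cy5. Per the labels the deposited values are log2 ratios of the red to the green channel, and the authors fitted a global normalisation model and then mixed models gene by gene in SAS, with t-tests of adjusted means and a Bonferroni threshold. The deposited log2 ratios were not centred, with array medians from -3.256 to 1.206, so they were taken as made before that normalisation. The scanner settings, background handling and spot filter are not given in the sources used here. Only deposited ratios were used, without spot intensities, so background correction, intensity-dependent normalisation and a filter on dim probes were not possible. The number of loops limits precision.

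Each array held 14112 spots. Of these, 12152 carried a gene name, as 6076 probes for 5397 genes with 2 spots each. The other 1960 (980 probes) carried none and were left out of the main analysis. Gene IDs matched the reference annotation for 12112 named spots and not for 40. Probes of the 595 genes with several were kept apart as features. At 6, 12 and 48 h, 138, 203 and 49 of these genes had a probe that passed. All probes passed one way for 28, 42 and 2. The reference was used for names only and no coordinates are given, since the build behind the probes is not stated. Ratios at a shared upper limit, 2969 in all and 6 to 74 per array, were set to missing as failed spots, 480 of them in named spots. Between 76 and 783 values per array were missing as deposited.

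The pairing of extracts came from the sample labels, which state strain, surface, time, growth form, replicate and dye of each extract. Every array joined 2 extracts of one replicate of one combination, so the unit of replication was the loop of 12 arrays, and the replicate was a block by construction. Each array was centred on its median and repeat spots were averaged. Dye-swap arrays were turned to one orientation and averaged, and a pair of extracts had a value only where both orientations did. The 6 extracts of a loop were then solved by least squares for each feature, with at least 5 of 6 pairs present. A feature was tested with values in at least 6 of 8 loops and in every combination. The differences of the loops were fitted in limma with a coefficient for each of the 4 combinations (lmFit and eBayes, 4 residual degrees of freedom) and p-values were adjusted over features by Benjamini-Hochberg at 0.05. Comparisons over all loops are means of the 4 combinations, those within a combination are its coefficient, and those between strains or surfaces are differences of coefficients. Replicate numbers were also checked for a shared effect across combinations. For the average over times, the half-differences between replicates correlated above 0.1 in 6 of 6 pairs of combinations (median r 0.258), and for the other comparisons in 1 to 5 of 6, so a fit with a replicate block was run beside the main one.

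The 30 gene lists and the naming of genes were fixed before the data were examined, as were the main analysis and most alternatives. Lists were tested with camera of limma at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of one comparison. Members were counted past the test over all features and again adjusted over the list alone. Named genes are the 10 largest differences in each direction with a standard symbol and, except between strains, one sign in every loop. They are 5 in planktonic cells over time and up to 6 between times, surfaces or strains. Up to 4 members with the smallest p of each list described are named too. Alternatives planned were no centring, arrays scaled to one spread, one mean over the loops, directly hybridised pairs alone, no filter or a strict filter on missing values, a Bonferroni threshold, unmoderated t-tests as in the methods, a replicate block, arrays as units and leaving out each loop. Alternatives added after the data were seen were centring each print block, including unnamed spots, and leaving out the weak dye-swap pairs in 2 versions.

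The fit was tested on simulated data with 6060 features. At 6 h it recovered 86.6% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes and called 7 of 5860 unchanged features. For GDH2346 against SC5314 it recovered 73.1%, 92.5% and 100% and called 12 unchanged features. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.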

Results

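Gene expression was followed during biofilm development in Candida albicans, a yeast that lives on human mucosa and grows as biofilms on medical devices. The series held 96 arrays with 2 dyes each, on which an extract of biofilm cells and an extract of planktonic (free-floating) cells were hybridised together. Cells were taken at 6, 12 and 48 h. There were 4 combinations of strain and surface, namely SC5314 on denture material, SC5314 on catheter material, GDH2346 on denture material and M61 on catheter material. SC5314 is the common reference strain of the species, and the other strains are given here by their labels. Each combination had 2 independent biological replicates, so that the arrays formed 8 closed loops of 12 arrays, with 6 extracts per loop and 48 extracts in all. The 6 extract pairs of a loop were each hybridised in both dye orientations, giving 24 groups of 4 arrays. The same extract pair measured in opposite dye orientations correlated across probes with a median r of -0.552 (range -0.882 to 0.316, 48 pairs), where a perfect dye swap would be fully negative. In 6 of the 48 pairs r lay above -0.1, and all of these held 48 h extracts of replicate 1. Repeat spots of one probe correlated with a median r of 0.730 over the arrays (range 0.129 to 0.929). Spot intensities were not used here, so no signal level can be given. Values below are log2 differences relative to the median gene of each array, over n = 8 loops unless another n is given. Their standard error (SE) in limma covers spread between replicates, not between combinations. Tested were 6060 features for 5388 genes.

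To see how attached cells differed early, biofilm and planktonic cells were compared at 6 h. The largest rise in biofilms was that of PGA6, which codes for a putative GPI-anchored surface protein, at 1.94 ± 0.16 or 3.84-fold. PDC11 (pyruvate decarboxylase) was higher by 1.70 ± 0.20, GDH3 (NADP-dependent glutamate dehydrogenase) by 1.65 ± 0.14, the ammonium permease gene MEP2 by 1.42 ± 0.14 and ERG10 (acetyl-CoA acetyltransferase) by 1.41 ± 0.12. ICL1, which codes for isocitrate lyase of the glyoxylate cycle, was lower by 4.08-fold (-2.03 ± 0.07). Lower values were also found for GAL10 of galactose use (-1.93 ± 0.16), the sorbose reductase gene SOU1 (-1.92 ± 0.17), the pH-response regulator RIM101 (-1.75 ± 0.20), the surface protease gene SAP9 (-1.68 ± 0.06) and PCK1 of gluconeogenesis (-1.65 ± 0.11). Each of these genes had the same sign in 8 of 8 loops, and the largest adjusted p among them was 0.002 (PDC11).

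Of the 30 fixed gene lists 13 passed camera at 6 h. Of 40 measured genes of ribosomal proteins, 30 rose and 10 did not pass, with 32 past the threshold adjusted over the list alone, and RPS6A reached 1.37 ± 0.07 and RPS23A 1.10 ± 0.10. The camera test gave this list an adjusted p of 1.09e-17, and an adjusted p = 0.247 with an estimated correlation. Among 50 genes of amino acid synthesis outside the sulphur pathway, 27 rose (29 adjusted over the list alone), with BAT22 at 1.28 ± 0.10 and HIS1 at 0.71 ± 0.05. For this list the adjusted p was 1.03e-11, with an adjusted p = 0.247 with an estimated correlation. In ergosterol synthesis 11 of 22 rose (13 adjusted over the list alone), ERG11 by 1.03 ± 0.13 and ERG1 by 0.73 ± 0.08, and in glycolysis 7 of 11 rose (8 adjusted over the list alone), FBA1 by 1.28 ± 0.15 and ENO1 by 1.25 ± 0.11. Camera gave these lists adjusted p-values of 3.56e-06 and 6.78e-05, and both had an adjusted p = 0.247 with an estimated correlation. Cell cycle genes rose in 7 of 25 cases (11 up and 2 down adjusted over the list alone), among them the cyclin gene CLN3 (0.95 ± 0.14) and the septin gene CDC10 (0.72 ± 0.08). Camera gave an adjusted p of 0.0179, and an adjusted p = 0.247 with an estimated correlation. The list of DNA replication and histones held 3 genes that rose and 1 that fell of 19 (5 and 1 adjusted over the list alone), with the ribonucleotide reductase genes RNR1 at 1.06 ± 0.09 and RNR22 at 1.08 ± 0.11 and the histone gene HHT1 at -0.35 ± 0.06. It had an adjusted p of 0.0179 and an adjusted p = 0.443 with an estimated correlation. Ribosome biogenesis had 8 genes that rose and 1 that fell of 57, the same adjusted over the list alone, with CIC1 at 0.48 ± 0.08 and RPA135 at -0.32 ± 0.05, and its median of 0.096 was -0.013 without centring. This list's adjusted p was 0.000188, with an adjusted p = 0.521 with an estimated correlation.

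Lower in biofilms at 6 h were 5 of 9 genes of gluconeogenesis and the glyoxylate cycle (6 down and 1 up adjusted over the list alone), including the carnitine acetyltransferase gene CTN1 at -0.85 ± 0.07 and the dicarboxylate transporter gene JEN2 at -0.67 ± 0.08. The list had an adjusted p of 9.14e-05, with an adjusted p = 0.247 with an estimated correlation. Of 16 hexose transporter genes 8 fell, also 8 adjusted over the list alone, with HGT7 at -1.38 ± 0.12 and HGT12 at -1.03 ± 0.15. Its adjusted p was 7.15e-06, with an adjusted p = 0.188 with an estimated correlation. In peroxisomal fatty acid breakdown 5 of 19 fell, also 5 adjusted over the list alone, with FOX2 at -1.63 ± 0.14 and PXA2 at -0.46 ± 0.05, and in the TCA cycle 5 of 13 fell, also 5 adjusted over the list alone, with MDH1 at -1.20 ± 0.13 and CIT1 at -0.69 ± 0.07. Both passed camera at adjusted p-values of 0.000338 and 0.046, with an adjusted p = 0.247 and an adjusted p = 0.521 with an estimated correlation. Storage carbohydrate genes fell in 4 of 12 cases, also 4 adjusted over the list alone, with the glycogen synthase gene GSY1 at -1.25 ± 0.10 and TPS2 of trehalose synthesis at -0.77 ± 0.07. Their adjusted p was 0.019, with an adjusted p = 0.521 with an estimated correlation. Adhesins of the ALS family fell in 3 of 7 cases (4 adjusted over the list alone), ALS3 by -1.51 ± 0.19 and ALS9 by -1.28 ± 0.19, while ALS1 at -1.81 ± 0.63 did not pass. For them the adjusted p was 0.0179, with an adjusted p = 0.326 with an estimated correlation. Members of the ALS, SAP, LIP and HGT families and paralogues of one ribosomal protein share sequence, so their probes are open to cross-hybridisation here and in every comparison.

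In all, 886 features passed limma's test at 6 h, 520 higher and 366 lower in biofilms, and 27 of the higher and 42 of the lower ones exceeded 2-fold. Without centring, which shifted the median of all features to -0.11, the count was 491, with 189 higher and 302 lower. It was 580 without SC5314 denture replicate 1, 533 without SC5314 denture replicate 2 and 488 without SC5314 catheter replicate 1.

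At 12 h the difference between biofilm and planktonic cells was largest for GLY1, which codes for threonine aldolase, and for the nucleoside transporter gene CNT, both 2.44 higher in biofilms (SE 0.19 and 0.28). RPS6A of the small ribosomal subunit was higher by 5.16-fold (2.37 ± 0.16), RHR2 (glycerol-3-phosphatase) by 2.31 ± 0.17, CYS3 (cystathionine gamma-lyase) by 2.04 ± 0.21, the RNA helicase gene DED1 by 1.97 ± 0.16 and the purine-cytosine permease gene FCY21 by 1.89 ± 0.13. Lower in biofilms were RIM101 (-1.87 ± 0.15), SAP9 (-1.38 ± 0.16), FMP45 (-1.27 ± 0.20), the transporter gene CDR11 (-1.26 ± 0.19), the sodium pump gene ENA2 (-1.15 ± 0.08) and HSP104, which codes for a protein disaggregase (-1.11 ± 0.06). The largest adjusted p among these was 0.00762 (FMP45).

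Ribosome genes stood out among the lists at 12 h. Of the 40 ribosomal protein genes 34 rose (37 adjusted over the list alone), RPL21A by 1.79 ± 0.17 and RPS20 by 0.93 ± 0.09, and of 57 ribosome biogenesis genes 37 rose (40 adjusted over the list alone), the fibrillarin gene NOP1 by 1.45 ± 0.15 and RRN3 of RNA polymerase I initiation by 1.04 ± 0.08. These lists had adjusted p-values of 7.99e-20 and 5.22e-15, and both had an adjusted p = 0.573 with an estimated correlation. In sulphur amino acid synthesis 8 of 21 rose (10 up and 1 down adjusted over the list alone), CYS4 by 1.03 ± 0.16 and the sulfite reductase gene ECM17 by 0.76 ± 0.13, with a list median of 0.028 that was -0.0053 without centring. The adjusted p was 0.0289, with an adjusted p = 0.573 with an estimated correlation. In the other amino acid pathways 10 of 50 rose (10 up and 1 down adjusted over the list alone), with the glutamine synthetase gene GLN1 at 1.82 ± 0.31 and TRP5 at 0.41 ± 0.06, and in ergosterol synthesis 7 of 22 rose (8 adjusted over the list alone), with ERG3 at 0.34 ± 0.06. Both had an adjusted p of 0.0429, with an adjusted p = 0.586 and an adjusted p = 0.573 with an estimated correlation. ALS4 (0.51 ± 0.06) and ALS9 (1.03 ± 0.19) rose among 7 adhesin genes, 2 in all and also 2 adjusted over the list alone. For this list the adjusted p was 0.0429, with an adjusted p = 0.573 with an estimated correlation. Heat shock and chaperone genes went the other way, with 8 of 17 lower and 2 higher (9 and 2 adjusted over the list alone). HSP21 was at -0.77 ± 0.08, ASR1 at -0.63 ± 0.06 and the co-chaperone gene YDJ1 at 0.53 ± 0.06, and the list had an adjusted p of 0.0071 and an adjusted p = 0.573 with an estimated correlation.

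At 12 h 1108 features passed, 738 higher and 370 lower in biofilms, and 74 of the higher and 19 of the lower ones exceeded 2-fold. The count was 695 without SC5314 denture replicate 1, 598 without GDH2346 denture replicate 1 and 621 without GDH2346 denture replicate 2, and 321 without the weak dye-swap pairs on equal loops. Of the 3 probes of GLY1 3 passed, while for the RNA helicase gene DBP2 1 of 2 passed, at 1.83 ± 0.20.

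At 48 h the genes lower in biofilms were led by ECM17, the sulfite reductase gene, at -1.92 ± 0.12 (3.77-fold), and ALD5, which codes for an aldehyde dehydrogenase, at -1.91 ± 0.17. OLE1, the fatty acid desaturase gene, was at -1.23 ± 0.10, the eisosome gene PIL1 at -1.17 ± 0.12 and ADE13 of purine synthesis (adenylosuccinate lyase) at -1.08 ± 0.13. CTN1 was at -1.83 ± 0.24 and the catalase gene CAT1 at -1.30 ± 0.17. The transcription factor gene CRZ2 was higher in biofilms by 1.68 ± 0.16 (3.21-fold), and both of its 2 probes passed. SSU1, the sulfite pump gene, was higher by 0.52 ± 0.06. The largest adjusted p was 0.0106 (CTN1), and ECM17 ran from -3.59 to -0.17 over the loops. The call of CTN1 was lost without SC5314 denture replicate 2 (adjusted p 0.0691), and that of CAT1 without each replicate of SC5314 denture (largest adjusted p 0.0748). FMP45 (-1.39 ± 0.25), JEN2 (-1.31 ± 0.23), HGT19 (-1.05 ± 0.20) and the phosphatase gene PTP2 (0.60 ± 0.11) passed too, but each lost its call in 6 of 8 left-out loops (largest adjusted p 0.156).

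Among the lists at 48 h, 7 of 24 proteasome genes fell (12 adjusted over the list alone), with RPN10 at -0.73 ± 0.10 and RPN8 at -0.56 ± 0.08. Camera gave an adjusted p of 7.32e-06, and an adjusted p = 0.71 with an estimated correlation. Without SC5314 denture replicate 2 these 2 genes had adjusted p-values of 0.0946 and 0.0945, and PRE5 and PRE9 lost their calls in 6 and 4 of 8 left-out loops. In gluconeogenesis and the glyoxylate cycle 4 of 9 fell (5 adjusted over the list alone), of ribosomal proteins 4 of 40 fell (9 adjusted over the list alone), with RPL18 at -0.78 ± 0.08 (n = 7 loops), and in glycolysis 2 of 11 fell (4 adjusted over the list alone), with FBA1 at -0.74 ± 0.09 and ENO1 at -0.54 ± 0.09. Many of these calls were lost with a loop left out, in 6 of 8 left-out loops for JEN2, 5 for ICL1 and 4 for CTN3, 7 for RPS20 and 5 for RPL11, and 5 for ENO1 (largest adjusted p 0.127) and 1 for FBA1 (0.0575). The adjusted p-values of these 3 lists were 5.76e-05, 0.000254 and 0.0416, and each had an adjusted p = 0.71 with an estimated correlation. Ribosome biogenesis genes and hypha-associated genes lay higher as lists, at medians of 0.064 and 0.099 that were -0.24 and -0.22 without centring, with 1 member past the threshold in each. Adjusted over the list alone, ribosome biogenesis kept 0 by limma and hypha-associated genes 2, and both lists had an adjusted p = 0.71 with an estimated correlation, against 0.00242 and 0.0174 with the preset one. The first of these members was CIC1 at 0.26 ± 0.05, which lost its call without any of the 8 loops (largest adjusted p 0.202), and the other the biofilm and hypha regulator TEC1 at 0.67 ± 0.13, lost in 7 of 8 (largest adjusted p 0.115).

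At 48 h 238 features passed, 30 higher and 208 lower in biofilms, of which 3 and 21 exceeded 2-fold. Without centring, which shifted the median of all features to -0.30, 4570 passed, 14 higher and 4556 lower, and with arrays scaled to one spread 100, 15 higher and 85 lower. Leaving out a loop gave 51 and 35 without SC5314 denture replicates 1 and 2, 78 and 72 without SC5314 catheter replicates 1 and 2, 146 without GDH2346 denture replicate 1, and 460 and 153 without M61 catheter replicates 1 and 2. The 6 extract pairs with weak dye swaps held extracts of this time, and without them the count was 399.

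**Figure D1:**
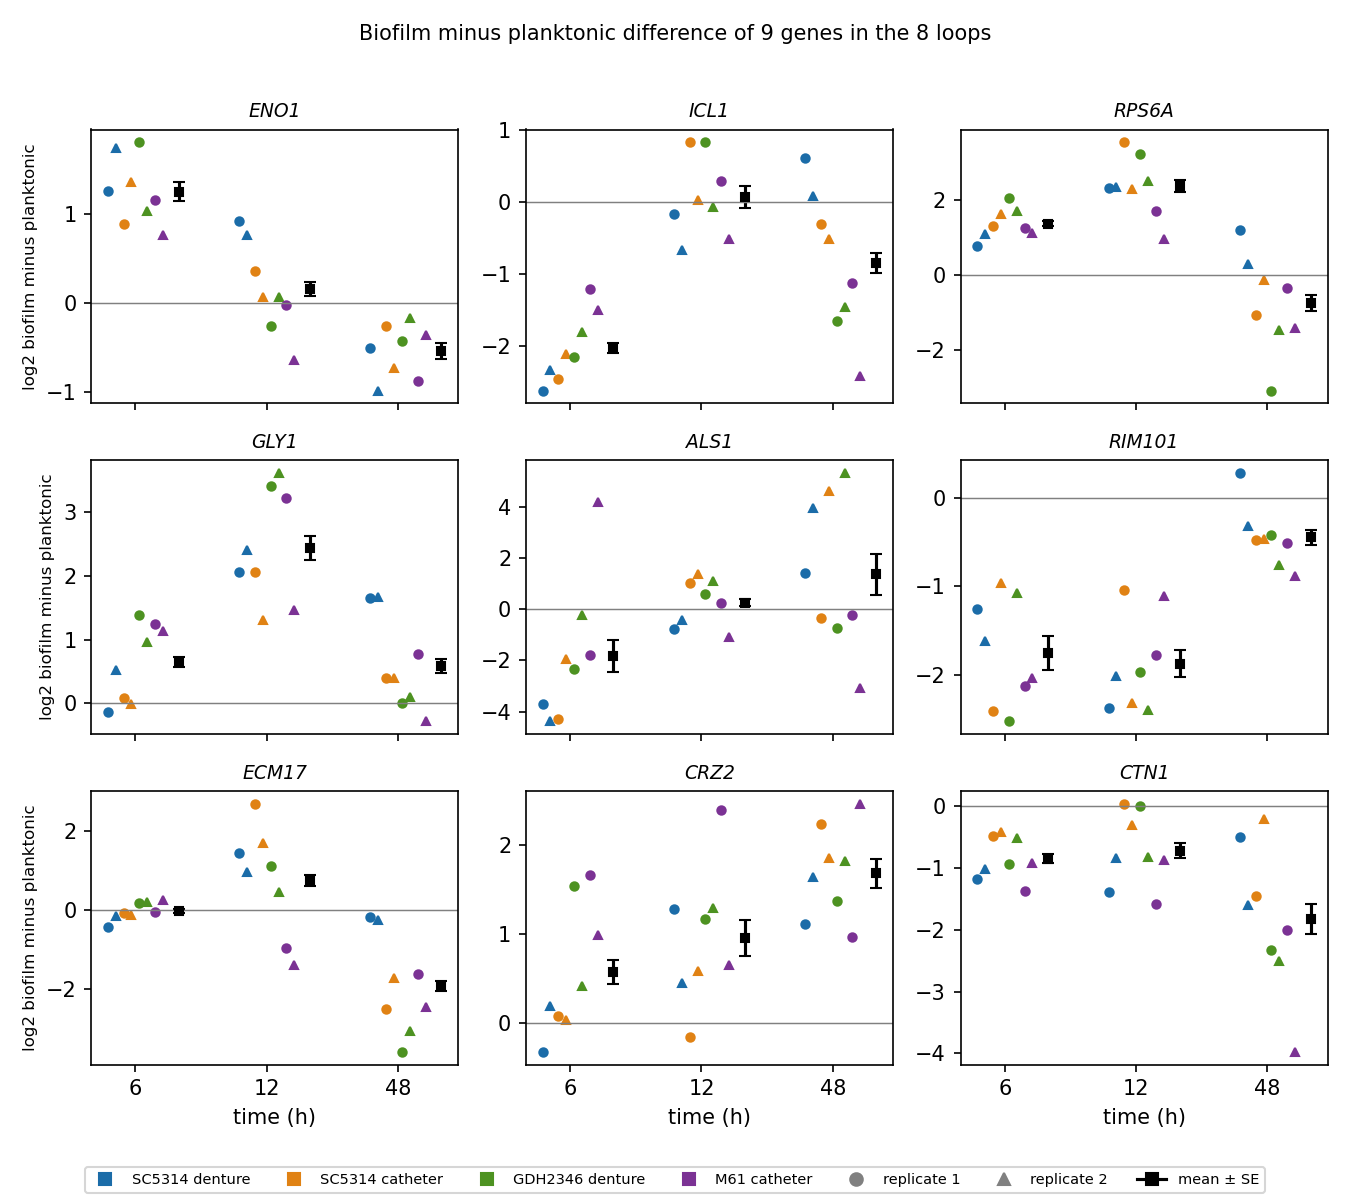
Log2 difference between biofilm and planktonic cells (vertical axis) of 9 genes at 6, 12 and 48 h (horizontal axis), with a coloured point per loop, coloured by strain and surface and shaped by replicate, and a black square for the mean with its SE. ENO1 went from 1.25 at 6 h to -0.54 at 48 h, and CRZ2 lay above 0 at every time, at 0.57, 0.96 and 1.68.

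Taking the 3 times together, features that passed in the same direction at 6, 12 and 48 h were 9 higher and 38 lower, where independent lists would share 0.313 and 0.767. CRZ2, GLY1, RHR2, FCY21 and the carbonic anhydrase gene NCE103 were among those higher at each time, and RIM101, SAP9, PIL1, SOU1, CTN1 and ALD5 among those lower at each time. These were chosen for naming here after their values were seen. The features higher at both 6 and 12 h numbered 226 (63.3 for independent lists) and those lower at both 126 (22.4). In opposite directions, 8 features were higher at 6 h and lower at 12 h (31.8 for independent lists) and 34 the reverse (44.6). Between 6 and 48 h, 9 features were higher at both (2.57) and 70 lower at both (12.6), while 37 were higher at 6 h and lower at 48 h (17.9) and 10 the reverse (1.81). Between 12 and 48 h, 20 were higher at both (3.65) and 68 lower at both (12.7), while 40 were higher at 12 h and lower at 48 h (25.3) and 1 the reverse (1.83). Arrays are shared between these comparisons, and unchanged extracts simulated on the same arrays gave r = -0.103 across genes between 6 and 12 h, -0.137 between 6 and 48 h and -0.11 between 12 and 48 h. At most 1 feature was called in these simulations, too few for a shared count. Between replicates that share no array, the difference at 6 h in one replicate and that at 12 h in the other correlated across genes at r = 0.463 and 0.355, those at 6 and 48 h at 0.136 and 0.0778 and those at 12 and 48 h at 0.0957 and 0.152. Genes are not independent replicates, so no p-value is given for these.

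Averaged over the 3 times, biofilm cells had 7 of 9 genes of gluconeogenesis and the glyoxylate cycle lower, also 7 adjusted over the list alone, with CTN1 at -1.13 ± 0.05, ICL1 at -0.94 ± 0.08 and PCK1 at -0.79 ± 0.03. The adjusted p was 2.38e-06, with an adjusted p = 0.21 with an estimated correlation. Of 16 hexose transporter genes 8 fell, also 8 adjusted over the list alone, with HGT19 at -0.89 ± 0.07 and HGT17 at -0.77 ± 0.05. Its adjusted p was 0.000553, with an adjusted p = 0.214 with an estimated correlation. Proteasome genes fell in 9 of 24 cases, also 9 adjusted over the list alone, with RPN10 at -0.32 ± 0.04 and RPT5 at -0.25 ± 0.02. For this list the adjusted p was 0.0047, with an adjusted p = 0.337 with an estimated correlation. Ribosomal protein genes rose in 32 of 40 cases (37 adjusted over the list alone), with RPS6A at 1.00 ± 0.07, and ribosome biogenesis genes in 36 of 57 (42 adjusted over the list alone), with CIC1 at 0.57 ± 0.05 and NSA2 at 0.40 ± 0.02. Both lists, at adjusted p-values of 2.57e-14 and 8.12e-14, had an adjusted p = 0.337 with an estimated correlation. Ergosterol genes rose in 13 of 22 cases (14 adjusted over the list alone) with ERG10 at 0.56 ± 0.04, and amino acid synthesis genes in 23 of 50 (30 adjusted over the list alone) with GDH3 at 0.67 ± 0.08 and TRP4 at 0.37 ± 0.04, though the list medians of 0.12 and 0.12 were -0.030 and -0.032 without centring. Glycolysis genes rose in 4 of 11 cases (8 adjusted over the list alone), with ENO1 at 0.29 ± 0.03, though FBA1 lost its call in 6 of 8 left-out loops (largest adjusted p 0.125) and PGI1 in 1 (0.0553). These 3 lists had adjusted p-values of 5.99e-05, 2.26e-06 and 0.00166, and each an adjusted p = 0.337 with an estimated correlation. Cell cycle genes had 9 higher and 1 lower of 25, the same adjusted over the list alone, with CLN3 at 0.68 ± 0.06, a median of 0.055 that was -0.097 without centring, and an adjusted p of 0.0499 (adjusted p = 0.337 with an estimated correlation).

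The average over times gave 1475 features, 837 higher and 638 lower in biofilms. Without centring, which shifted the median of all features to -0.15, 1451 passed, with 171 higher and 1280 lower. The count was 934 without SC5314 catheter replicate 2 and 982 without GDH2346 denture replicate 1, and 909 without the weak dye-swap pairs.

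Change over time was followed next within biofilms. From 6 to 12 h the glycolytic genes fell most, ENO1 (enolase) by -4.23 ± 0.15 or 18.8-fold, FBA1 (aldolase) by -3.95 ± 0.21 and PGK1 (phosphoglycerate kinase) by -3.23 ± 0.11, together with PDC11 (-3.70 ± 0.26) and GND1 of the pentose phosphate pathway (-2.95 ± 0.19). The histone genes HTA1 (-2.01 ± 0.09) and HHF22 (-2.02 ± 0.22) and the disulfide isomerase gene PDI1 (-2.13 ± 0.13) fell too. The adhesin gene ALS1 rose by 3.78 ± 0.44 or 13.8-fold at the probe named by rule, and both of its 2 probes passed. ICL1 rose by 2.76 ± 0.14, NCE103 by 2.25 ± 0.20, CAT1 by 2.06 ± 0.12, FOX2 by 2.03 ± 0.20 and CTN1 by 1.92 ± 0.15. ALS3 rose by 2.53 ± 0.16 at 1 of its 2 probes, the other being at 0.072. The largest adjusted p among these was 0.000951 (ALS1).

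By list, 10 of 11 glycolysis genes fell in biofilms from 6 to 12 h (11 adjusted over the list alone), with a median of -1.45, as did 31 of 50 amino acid synthesis genes (31 down and 1 up adjusted over the list alone), BAT22 by -1.74 ± 0.07 and GDH3 by -1.63 ± 0.09. Ribosome biogenesis genes rose in 35 of 57 cases (39 adjusted over the list alone), DBP2 by 1.65 ± 0.10 and NOP1 by 1.15 ± 0.08. The adjusted p-values of these 3 lists were 1.07e-13, 1.07e-13 and 2.23e-18, and each had an adjusted p = 0.0586 with an estimated correlation. Genes of DNA replication and histones fell in 9 of 19 cases (11 adjusted over the list alone), RNR1 by -1.42 ± 0.10, and cell cycle genes in 10 of 25 (14 down and 1 up adjusted over the list alone), the tubulin gene TUB2 by -1.52 ± 0.16. Their adjusted p-values were 1.01e-06 and 7.5e-05, with an adjusted p = 0.175 and an adjusted p = 0.13 with an estimated correlation. Ergosterol genes had 9 lower and 1 higher of 22 (12 and 1 adjusted over the list alone), ERG10 at -1.53 ± 0.13, and proteasome genes 8 lower and 1 higher of 24 (9 and 1 adjusted over the list alone), PRE9 at -0.52 ± 0.08 and the proteasome regulator gene RPN4 at 0.50 ± 0.09. Camera gave these lists adjusted p-values of 0.000153 and 5.1e-05, with an adjusted p = 0.152 and an adjusted p = 0.0586 with an estimated correlation. Genes of gluconeogenesis and the glyoxylate cycle rose in 5 of 9 cases (6 adjusted over the list alone), JEN2 by 1.64 ± 0.20, and those of fatty acid breakdown in 6 of 19 (8 adjusted over the list alone), with ANT1 at 0.65 ± 0.11. Adhesin genes rose in 4 of 7 cases, also 4 adjusted over the list alone, ALS9 by 1.20 ± 0.08. These 3 lists had adjusted p-values of 0.00075, 0.00187 and 0.00153, with an adjusted p = 0.277, an adjusted p = 0.296 and an adjusted p = 0.296 with an estimated correlation. Respiratory chain genes had 5 higher and 1 lower of 22 (8 and 1 adjusted over the list alone), with the alternative oxidase gene AOX1 at 0.55 ± 0.09, and ribosomal proteins 7 lower and 1 higher of 40, the same adjusted over the list alone, with RPL4B at -0.41 ± 0.07 and RPP1 at 0.40 ± 0.07. Both passed camera at adjusted p-values of 0.0196 and 0.0012, with an adjusted p = 0.564 and an adjusted p = 0.481 with an estimated correlation.

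From 6 to 12 h 1138 features passed in biofilms, 598 higher and 540 lower at 12 h, and 56 and 83 of them exceeded 2-fold. Without centring, which shifted the median of all features to 0.12, 1142 passed, 822 higher and 320 lower, and without the weak dye-swap pairs on equal loops 627.

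From 12 to 48 h in biofilms RPS6A fell by -2.79 ± 0.25 or 6.93-fold, URA2 of pyrimidine synthesis by -2.69 ± 0.13, RPL18 by -2.51 ± 0.11 (n = 7 loops), CNT by -2.30 ± 0.22, ALS1 by -2.28 ± 0.22 and RHR2 by -2.22 ± 0.12. TEF2 (-2.22 ± 0.11) and TEF1 (-2.01 ± 0.09), which code for translation elongation factor 1-alpha, and ALS3 (-2.07 ± 0.06) fell as well, and both probes of ALS1 and of ALS3 passed. HSP104 rose by 1.57 ± 0.14 or 2.97-fold with 3 of its 3 probes past the threshold. RIM101 rose by 1.24 ± 0.21, the glycerophosphocholine transporter gene GIT3 by 1.20 ± 0.16, the sterol glucosyltransferase gene UGT51C1 by 1.15 ± 0.15 and the small heat shock gene HSP21 by 0.90 ± 0.14. The largest adjusted p among these was 0.00478 (RIM101). GAL10 (0.65 ± 0.13) had an adjusted p of 0.0534 without SC5314 denture replicate 1.

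Ribosomal protein genes fell in 31 of 40 cases from 12 to 48 h (33 adjusted over the list alone), with a list median of -0.99, RPL5 at -1.72 ± 0.10 and RPS20 at -1.29 ± 0.07. Ribosome biogenesis genes fell in 30 of 57 (37 adjusted over the list alone), with a median of -0.32, DBP2 at -1.75 ± 0.11 and NOP1 at -1.58 ± 0.08. The adjusted p-values were 1.08e-25 and 1.91e-14, with an adjusted p = 0.215 and an adjusted p = 0.361 with an estimated correlation. Adhesin genes fell in 4 of 7 cases, also 4 adjusted over the list alone, with ALS9 at -1.30 ± 0.13. Camera gave an adjusted p of 0.000576, and an adjusted p = 0.215 with an estimated correlation. Respiratory chain and ATP synthase genes fell in 9 of 22 cases, also 9 adjusted over the list alone, ATP2 by -1.36 ± 0.15 and ATP4 by -1.11 ± 0.10. Its adjusted p was 0.0123, with an adjusted p = 0.615 with an estimated correlation. In sulphur amino acid synthesis 7 of 21 fell (9 adjusted over the list alone), ECM17 by -1.93 ± 0.12 and CYS3 by -1.72 ± 0.16, and in the other amino acid pathways 11 of 50 fell (14 adjusted over the list alone), ARO4 by -0.70 ± 0.09. These lists had adjusted p-values of 0.0324 and 0.0228, with an adjusted p = 0.61 and an adjusted p = 0.458 with an estimated correlation.

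From 12 to 48 h 754 features passed in biofilms, 103 higher and 651 lower at 48 h, and 9 and 107 of them exceeded 2-fold. Without centring, which shifted the median of all features to -0.22, 1840 passed, 24 higher and 1816 lower, and without the weak dye-swap pairs on equal loops 495.

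Planktonic cells were followed over the same times. From 6 to 12 h ENO1 fell by -3.14 ± 0.07 or 8.79-fold, the hexose transporter gene HGT7 by -3.13 ± 0.18, FBA1 by -2.71 ± 0.08, PDC11 by -2.47 ± 0.16 and PGK1 by -2.40 ± 0.09. CTN1 rose by 1.79 ± 0.21, CAT1 by 1.49 ± 0.09, ALD5 by 1.33 ± 0.11 and CTN3, a further carnitine acetyltransferase gene, by 0.96 ± 0.12. Their largest adjusted p was 0.00297 (CTN3).

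Of the lists, 9 of 11 glycolysis genes fell in planktonic cells from 6 to 12 h (10 adjusted over the list alone), with TDH3 at -1.46 ± 0.08. For this list the adjusted p was 1.85e-16, with an adjusted p = 0.173 with an estimated correlation. Amino acid synthesis genes fell in 22 of 50 cases (28 adjusted over the list alone), ILV6 by -1.10 ± 0.08, and ribosomal protein genes in 15 of 40 (25 down and 1 up adjusted over the list alone), RPL4B by -1.21 ± 0.08. Their adjusted p-values were 1.27e-11 and 4.85e-11, with an adjusted p = 0.336 and an adjusted p = 0.399 with an estimated correlation. Storage carbohydrate genes fell in 4 of 12 cases (7 adjusted over the list alone; UGP1 lost its call in 7 of 8 left-out loops), GSY1 by -1.06 ± 0.07, and yeast-form genes in 2 of 9 (5 adjusted over the list alone), with the wall protein gene PIR1 at -0.59 ± 0.06. Both had an adjusted p of 0.000702, with an adjusted p = 0.216 and an adjusted p = 0.173 with an estimated correlation. Cell wall genes had 12 lower and 2 higher of 39 (12 and 3 adjusted over the list alone), with the chitinase gene CHT3 at -1.08 ± 0.06, and cell cycle genes fell in 5 of 25, also 5 adjusted over the list alone, with TUB2 at -0.88 ± 0.08. Camera gave these lists adjusted p-values of 0.00908 and 0.0123, and both had an adjusted p = 0.399 with an estimated correlation. The histone genes HTA1 (-2.19 ± 0.07) and HTB1 (-1.97 ± 0.11) were among 5 of 19 genes of DNA replication and histones that fell (6 adjusted over the list alone), a list whose median of -0.032 was 0.0079 without centring. It had an adjusted p of 0.00524 and an adjusted p = 0.336 with an estimated correlation, and proteasome genes, 4 of 24 lower and also 4 adjusted over the list alone with PRE9 at -0.39 ± 0.05, had 0.000677 and an adjusted p = 0.184 with an estimated correlation. Respiratory chain genes had 7 higher and 1 lower of 22 (10 and 2 adjusted over the list alone), CYT1 at 0.88 ± 0.08, and gluconeogenesis and the glyoxylate cycle 5 higher and 1 lower of 9, the same adjusted over the list alone, ICL1 at 0.67 ± 0.11. Both passed camera at adjusted p-values of 0.000789 and 0.01, with an adjusted p = 0.173 and an adjusted p = 0.478 with an estimated correlation. Ribosome biogenesis lay higher as a list at a median of 0.093 with 2 of 57 past the threshold and 0 by limma adjusted over the list alone. Camera gave an adjusted p of 0.000215, and an adjusted p = 0.566 with an estimated correlation. These members, NSA2 and IMP4, each lost their call in 7 of 8 left-out loops (largest adjusted p 0.156 and 0.124).

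From 6 to 12 h 523 features passed in planktonic cells, 126 higher and 397 lower at 12 h, and 142 higher and 272 lower without centring. The count was 327 and 335 without SC5314 denture replicates 1 and 2 and 346 without SC5314 catheter replicate 1, and 222 without the weak dye-swap pairs on equal loops. Of the features that fell in biofilms over this interval 237 also fell in planktonic cells (35.4 for independent lists), and 76 rose in both (12.4 for independent lists). Unchanged simulated extracts gave r = 0.17 across genes from shared arrays, with 0 and 0 features called in limma, too few for a shared count. Across replicates that share no array the changes in biofilm and planktonic cells correlated across genes at r = 0.422 and 0.517.

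From 12 to 48 h fewer changes passed in planktonic cells. CTN1 rose by 1.58 ± 0.16, the glycine cleavage gene GCV2 by 1.49 ± 0.09, DED1 by 1.46 ± 0.15 and JEN2 by 1.31 ± 0.16. ALS1 fell most, by -3.38 ± 0.60 or 10.4-fold at the probe named by rule, with both of its 2 probes past the threshold, but lost its call in 4 of 8 left-out loops (largest adjusted p 0.199). PIL1 fell by -1.55 ± 0.08 or 2.92-fold, the peroxiredoxin gene PRX1 by -1.45 ± 0.12, SOU1 by -1.03 ± 0.12 and ALS3 by -1.45 ± 0.14, the latter at 1 of 2 probes. The largest adjusted p among these was 0.0381 (ALS1). Proteasome genes rose in 2 of 24 cases (8 adjusted over the list alone), with PRE9 at 0.47 ± 0.07 and RPN10 at 0.39 ± 0.07, whose calls were lost in 4 and 5 of the 8 left-out loops (largest adjusted p 0.0968 without M61 catheter replicate 2 and 0.181 without M61 catheter replicate 1). The list's adjusted p was 2.54e-06, with an adjusted p = 0.546 with an estimated correlation. Genes of gluconeogenesis and the glyoxylate cycle rose in 3 of 9 cases, also 3 adjusted over the list alone (ACH1 lost its call in 6 of 8 left-out loops), although the list's median was -0.016 and 0.031 without centring. Its adjusted p was 0.0406, with an adjusted p = 0.792 with an estimated correlation. Hypha-associated genes fell in 2 of 22 cases, also 2 adjusted over the list alone. For this list the adjusted p was 0.00747, with an adjusted p = 0.605 with an estimated correlation. Respiratory chain and ribosome biogenesis genes lay lower as lists, at medians of -0.064 and -0.063, with 0 members past limma's test over all features and 5 and 0 adjusted over the list alone. These lists had adjusted p-values of 0.00385 and 0.00747, with an adjusted p = 0.546 and an adjusted p = 0.705 with an estimated correlation.

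From 12 to 48 h 77 features passed in planktonic cells, 47 higher and 30 lower at 48 h (567 at an unadjusted p under 0.05). Without centring 182 passed, 129 higher and 53 lower, with arrays scaled to one spread 42, 19 higher and 23 lower, with one mean over the loops 40, and without the weak dye-swap pairs on equal loops 12. The count was 47 without SC5314 catheter replicate 2, 144 and 157 without GDH2346 denture replicates 1 and 2, and 39 and 37 without M61 catheter replicates 1 and 2.

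**Figure D2:**
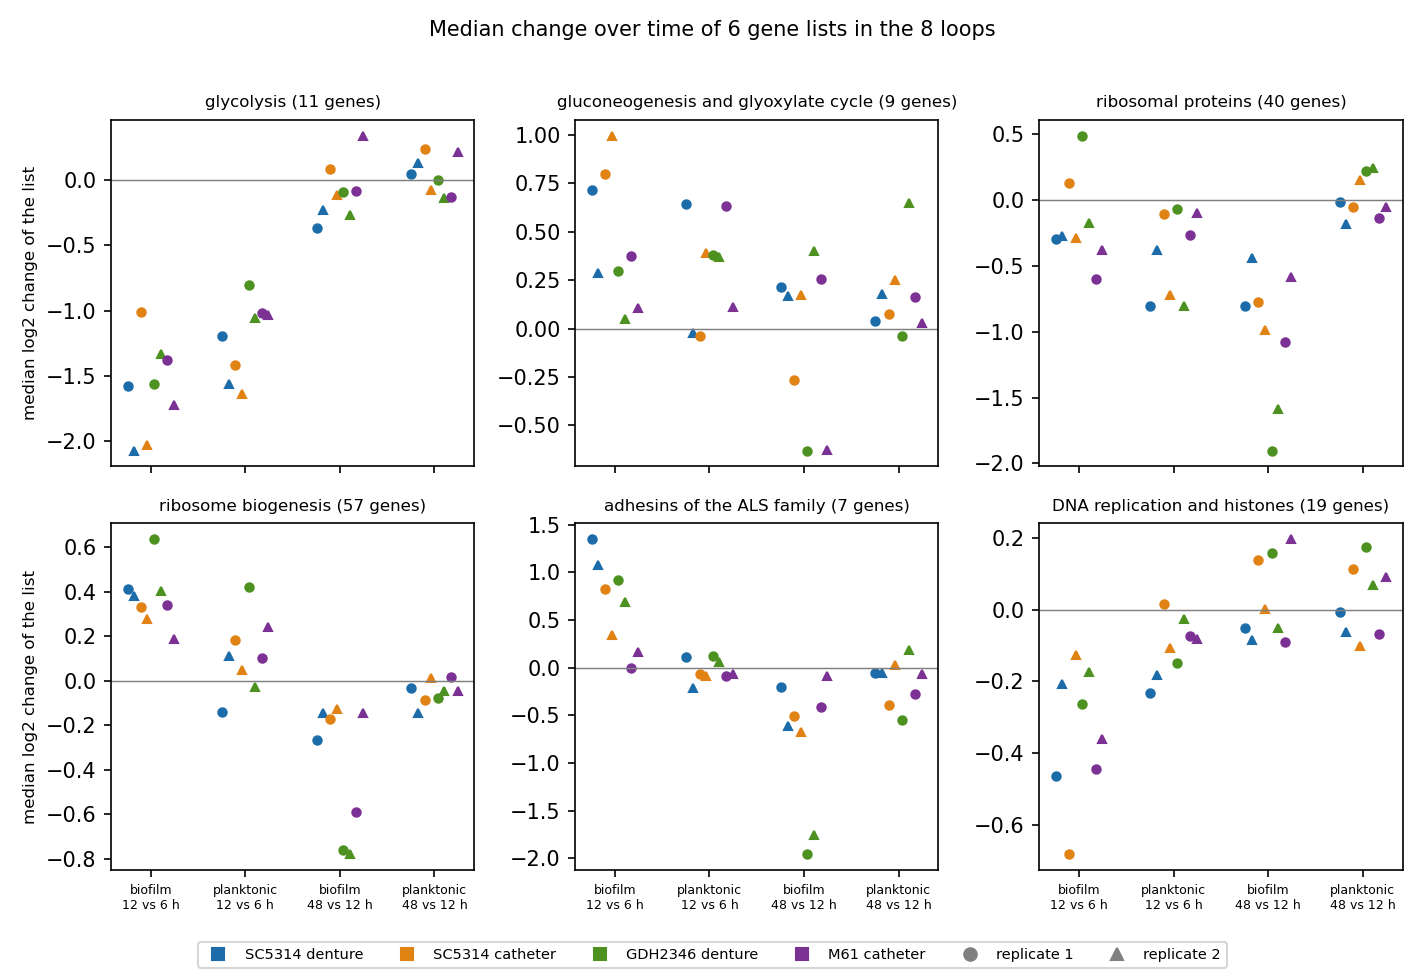
Median log2 change of 6 gene lists (vertical axis, a panel per list) in biofilm and planktonic cells from 6 to 12 h and from 12 to 48 h (horizontal axis), with a point per loop coloured by strain and surface and shaped by replicate. The ribosomal protein medians in biofilms from 12 to 48 h lie between -1.90 and -0.44, and those of ribosome biogenesis between -0.78 and -0.13.

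Whether the difference between biofilm and planktonic cells itself changed was tested between times. From 6 to 12 h it rose most for HGT7, by 3.07 ± 0.22, followed by the glycerol-3-phosphate dehydrogenase gene GUT2 (2.38 ± 0.11), ALS9 (2.31 ± 0.17, 3 of 4 probes past the threshold), CNT (2.13 ± 0.24), ICL1 (2.10 ± 0.19) and the peptide transporter gene PTR22 (2.05 ± 0.09). It fell most for PGA6 (-1.52 ± 0.24), MEP2 (-1.30 ± 0.16), the chaperone gene HSP90 (-1.27 ± 0.11), BAT22 (-1.20 ± 0.14), ENO1 (-1.10 ± 0.15) and PDI1 (-1.04 ± 0.15). The largest adjusted p was 0.0109 (PGA6). By list, the difference rose for 17 of 57 ribosome biogenesis genes (25 adjusted over the list alone), with RPA135 at 1.17 ± 0.10, and 9 of 40 ribosomal protein genes (12 adjusted over the list alone), with RPL18 at 0.94 ± 0.07 (n = 7 loops). Their adjusted p-values were 1.6e-10 and 6.82e-05, with an adjusted p = 0.34 and an adjusted p = 0.254 with an estimated correlation. It rose for 3 of 7 adhesin genes (4 adjusted over the list alone) and 4 of 19 fatty acid breakdown genes (7 adjusted over the list alone), with FOX2 at 1.53 ± 0.22, at adjusted p-values of 0.000633 and 0.000831, both with an adjusted p = 0.198 with an estimated correlation.

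The difference fell from 6 to 12 h for 12 of 50 amino acid synthesis genes (16 down and 1 up adjusted over the list alone), with GDH3 at -1.43 ± 0.15, and for 7 of 11 glycolysis genes with HXK2 (0.69 ± 0.10) going up (8 and 1 adjusted over the list alone). Camera gave these lists adjusted p-values of 5.93e-07 and 1.45e-05, with an adjusted p = 0.254 and an adjusted p = 0.258 with an estimated correlation. Heat shock genes fell in 5 of 17 cases (7 adjusted over the list alone), with KAR2 at -0.93 ± 0.14, and genes of DNA replication and histones in 3 of 19, also 3 adjusted over the list alone, with RNR1 at -1.04 ± 0.09. Both passed camera at adjusted p-values of 0.001 and 0.00191, both with an adjusted p = 0.198 with an estimated correlation. Ergosterol genes fell in 2 of 22 cases (6 adjusted over the list alone) and cell cycle genes had 2 higher and 2 lower of 25 (2 and 5 adjusted over the list alone), with CHT3 at 0.69 ± 0.10. In left-out loops ERG3 lost its call in 8 of 8, KIP1 in 6, and CDC10 and CDC11 in 4. These lists had adjusted p-values of 0.000921 and 0.0355, with an adjusted p = 0.354 and an adjusted p = 0.415 with an estimated correlation. In all 491 features passed, 316 higher and 175 lower, and 439 without centring, 336 higher and 103 lower. The count was 232 and 296 without SC5314 denture replicates 1 and 2, 285 and 312 without GDH2346 denture replicates 1 and 2, and 193 without the weak dye-swap pairs on equal loops.

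From 12 to 48 h the difference between biofilm and planktonic cells fell by -3.11 ± 0.31 for RPS6A, -2.85 ± 0.19 for URA2, -2.68 ± 0.18 for RPL18 (n = 7 loops), -2.67 ± 0.21 for ECM17 and -2.32 ± 0.21 for IFH1, a co-regulator of ribosomal protein genes. It rose for RIM101 (1.43 ± 0.19), HSP104 (1.30 ± 0.15), STB3 (1.00 ± 0.14), the calcium channel gene MID1 (0.80 ± 0.09, n = 7 loops) and GRP2 (0.73 ± 0.10, 1 of 2 probes). The largest adjusted p was 0.00594 (STB3). Ribosomal protein genes fell in 31 of 40 cases (32 adjusted over the list alone), with RPS8A at -1.91 ± 0.13, and ribosome biogenesis genes in 23 of 57 (29 down and 1 up adjusted over the list alone), with RRN3 at -1.20 ± 0.08. Their adjusted p-values were 6.93e-21 and 8.94e-09, both with an adjusted p = 0.447 with an estimated correlation. Sulphur amino acid genes fell in 7 of 21 cases (8 adjusted over the list alone), with CYS4 at -1.38 ± 0.20, other amino acid synthesis genes in 7 of 50 (12 down and 1 up adjusted over the list alone), with GLN1 at -2.23 ± 0.31, and proteasome genes in 5 of 24, also 5 adjusted over the list alone, with RPN8 at -0.60 ± 0.10, though PRE8, PRE9 and RPN10 lost their calls in 6 of 8 left-out loops. The adjusted p-values of these 3 lists were 0.0299, 0.021 and 0.021, each with an adjusted p = 0.447 with an estimated correlation. In all 662 features passed, 88 higher and 574 lower, and without centring, which shifted the median of all features to -0.27, 1756 passed, 19 higher and 1737 lower. The count was 359 without SC5314 denture replicate 1 and 439 without SC5314 catheter replicate 1, 274 without the weak dye-swap pairs and 381 with one mean over the loops.

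**Figure D3:**
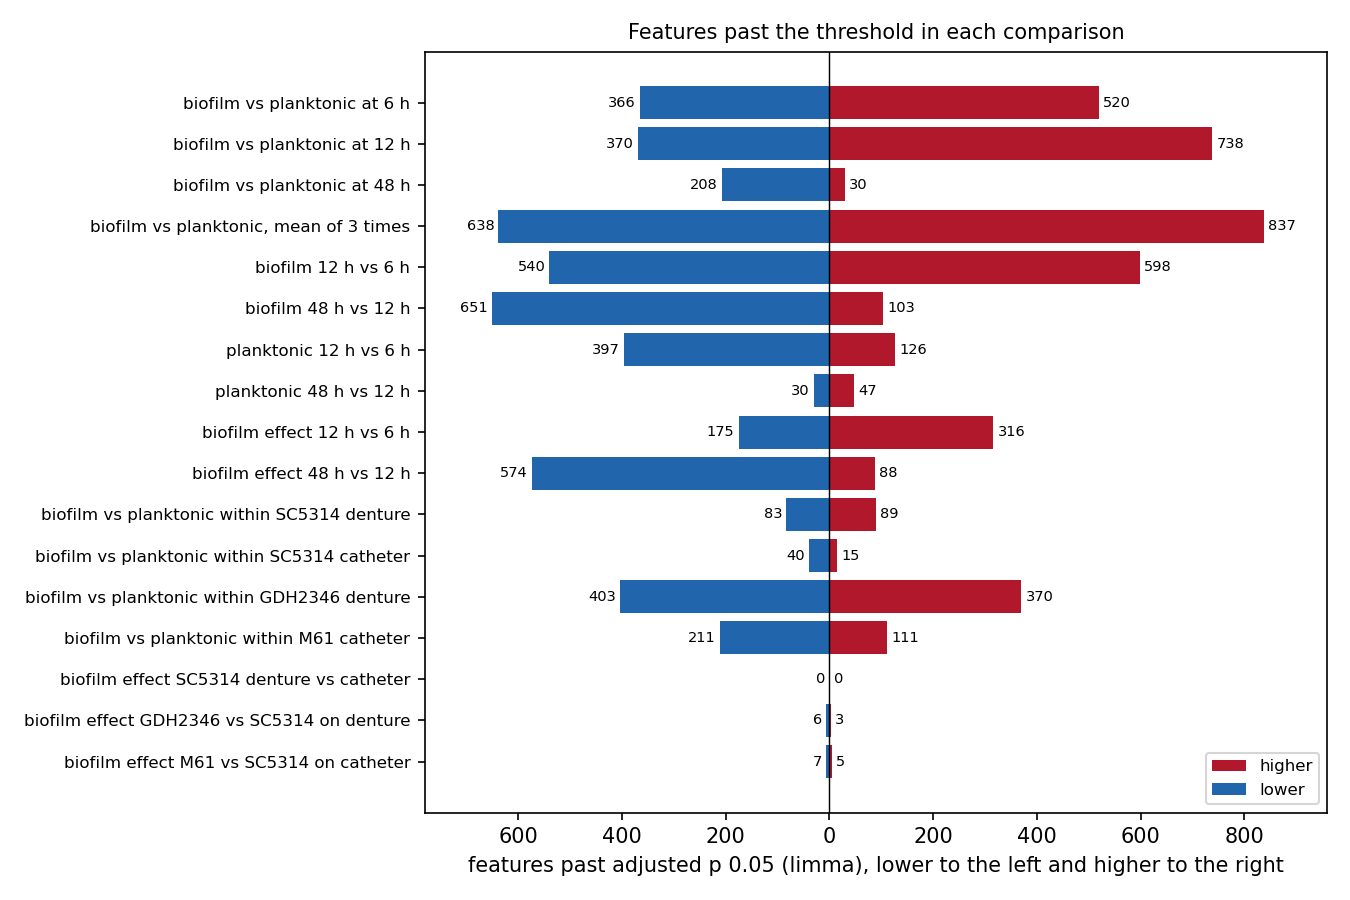
Number of features past an adjusted p of 0.05 in limma (horizontal axis, lower to the left in blue and higher to the right in red) for each comparison (vertical axis). The bars range from 0 for SC5314 on denture against catheter to 837 higher and 638 lower for the average of the 3 times.

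The average over times was then examined within each strain and surface, where each value rests on 2 loops and on a spread shared by all 8. In GDH2346 on denture material the chaperone gene HSP78 was at -1.01 ± 0.05, FOX2 at -1.28 ± 0.12, CTN1 at -1.18 ± 0.10 and NSA2 of ribosome biogenesis at 0.67 ± 0.04 (n = 2 loops each). Of 57 ribosome biogenesis genes 36 rose (42 adjusted over the list alone) and of 40 ribosomal protein genes 20 rose (32 adjusted over the list alone), at adjusted p-values of 2.93e-18 and 1.45e-13, with an adjusted p = 0.284 and an adjusted p = 0.552 with an estimated correlation. Gluconeogenesis and glyoxylate genes fell in 6 of 9 cases and hexose transporter genes in 8 of 16, the same adjusted over the list alone, with HGT18 at -0.70 ± 0.06. Camera gave these lists adjusted p-values of 1.28e-05 and 0.00102, both with an adjusted p = 0.224 with an estimated correlation. Heat shock genes had 6 lower and 2 higher of 17 (7 and 2 adjusted over the list alone) with ASR2 at -0.84 ± 0.07, and fatty acid breakdown genes fell in 6 of 19, also 6 adjusted over the list alone, at adjusted p-values of 0.0128 and 0.0327, both with an adjusted p = 0.284 with an estimated correlation. In all 773 features passed, 370 higher and 403 lower, but 45 without replicate 1 of this combination and 299 without replicate 2. The count was 392 without centring, 161 higher and 231 lower. Without the weak dye-swap pairs a lone loop of GDH2346 is left, as of M61, so no count is given.

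In M61 on catheter material CTN1 was at -1.79 ± 0.10, the hexose transporter gene HGT17 at -1.42 ± 0.10, ASR2 at -1.21 ± 0.07 and the wall protein gene RBT1 at 1.27 ± 0.12 (n = 2 loops each). ECE1, the candidalysin precursor gene, was at 0.48 ± 0.05, and 4 of 22 hypha-associated genes rose (6 up and 1 down adjusted over the list alone), with a list median of 0.14 that was -0.091 without centring. The adjusted p was 0.000206, with an adjusted p = 0.155 with an estimated correlation. Gluconeogenesis and glyoxylate genes fell in 5 of 9 cases (6 adjusted over the list alone), with ICL1 at -1.08 ± 0.17. Camera gave an adjusted p of 3.79e-07, and an adjusted p = 0.155 with an estimated correlation. TCA cycle genes fell in 4 of 13 cases (5 adjusted over the list alone), with CIT1 at -0.68 ± 0.07. Its adjusted p was 0.0191, with an adjusted p = 0.504 with an estimated correlation. Ergosterol genes rose in 4 of 22 cases (9 adjusted over the list alone), with ERG10 at 0.64 ± 0.08 and a median of 0.19 that was -0.044 without centring. For this list the adjusted p was 5.54e-07, with an adjusted p = 0.162 with an estimated correlation. In all 14 lists passed camera, and these 4 were chosen for fuller description after their values were seen. The others that lay higher were ribosome biogenesis (4 of 57 rose), ribosomal proteins (3 of 40), cell cycle (2 of 25), cell wall (5 of 39) and DNA replication and histones (2 of 19), and all of these but the ribosomal proteins had a median below 0 without centring. Those that lay lower were hexose transporters (3 of 16 fell), proteasome (4 of 24), fatty acid breakdown (1 of 19), heat shock (3 of 17) and adhesins (0 of 7). The adjusted p-values of these 10 lists ranged from 2.23e-10 to 0.0449, and from 0.162 to 0.504 with an estimated correlation. In all 322 features passed, 111 higher and 211 lower, and without centring, which shifted the median of all features to -0.22, 450 passed, 42 higher and 408 lower. The count was 173 and 183 without SC5314 catheter replicates 1 and 2, and 212 and 556 without M61 catheter replicates 1 and 2. It was 202 with directly hybridised pairs alone.

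In SC5314 on denture material LYS12 of lysine synthesis was at 0.75 ± 0.07, ERG10 at 0.74 ± 0.08, RPS6A at 1.34 ± 0.14 and CTN1 at -1.09 ± 0.10 (n = 2 loops each), though without one of the replicates of this combination their adjusted p-values reached 0.0612, 0.0894, 0.0979 and 0.0619. Amino acid synthesis genes rose in 9 of 50 cases (28 adjusted over the list alone), glycolysis genes in 3 of 11 (8 adjusted over the list alone) and ergosterol genes in 3 of 22 (9 adjusted over the list alone). These 3 passed camera at adjusted p-values of 1.24e-15, 3.71e-07 and 5.88e-05, each with an adjusted p = 0.249 with an estimated correlation, and were chosen for fuller description after their values were seen, out of 10 lists that passed. The others that lay higher were ribosomal proteins (2 of 40 rose), and ribosome biogenesis (1 of 57) and cell cycle (2 of 25), whose medians were below 0 without centring. Those that lay lower were gluconeogenesis and the glyoxylate cycle (4 of 9 fell), hexose transporters (2 of 16), fatty acid breakdown (2 of 19) and proteasome (1 of 24). The adjusted p-values of these 7 lists ranged from 9.5e-13 to 0.0344, and from 0.178 to 0.606 with an estimated correlation. In all 172 features passed, 89 higher and 83 lower, with the median of all features at -0.12 without centring. The count was 8 and 22 without SC5314 denture replicates 1 and 2, 102 and 107 without SC5314 catheter replicates 1 and 2, 101 and 99 without GDH2346 denture replicates 1 and 2, and 509 and 510 without M61 catheter replicates 1 and 2. It was 342 without the weak dye-swap pairs and 108 with directly hybridised pairs alone.

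In SC5314 on catheter material PCK1 was at -0.92 ± 0.06 (n = 2 loops), and RPS6A at 1.27 ± 0.14 had an adjusted p of 0.212 without replicate 2 of this combination. Gluconeogenesis and glyoxylate genes fell in 2 of 9 cases (5 adjusted over the list alone) and 1 of 40 ribosomal protein genes rose (15 adjusted over the list alone), at adjusted p-values of 4.69e-06 and 2.16e-13, with an adjusted p = 0.221 and an adjusted p = 0.546 with an estimated correlation. Of 5 lists that passed camera, the others were amino acid synthesis (0 of 50 rose), ribosome biogenesis (1 of 57) and ergosterol synthesis (1 of 22), which lay higher at medians of 0.14, 0.086 and 0.11 that were -0.073, -0.11 and -0.092 without centring. Their adjusted p-values were 1.76e-07, 4.19e-05 and 0.00096, with an adjusted p = 0.478, an adjusted p = 0.576 and an adjusted p = 0.478 with an estimated correlation. In all 55 features passed, 15 higher and 40 lower, and 102 with the replicate block, 33 higher and 69 lower. Without centring, which shifted the median of all features to -0.20, 149 passed, 17 higher and 132 lower, and with arrays scaled to one spread 45, 4 higher and 41 lower. The count was 8 and 9 without SC5314 catheter replicates 1 and 2, 30 and 29 without GDH2346 denture replicates 1 and 2, and 222 and 229 without M61 catheter replicates 1 and 2. It was 125 without the weak dye-swap pairs and 108 with unnamed spots included.

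No array joined different strains or surfaces, so only the biofilm minus planktonic difference could be compared between them, again as the average over times. The surfaces were compared within SC5314. LYS12 had the smallest adjusted p, 0.872, at a difference of 0.69 ± 0.09 between denture and catheter material, which did not pass. In limma 0 features passed and 191 had an unadjusted p under 0.05, while 0 passed in the methods' unmoderated test and 24 with arrays as units. As lists, the amino acid synthesis genes outside the sulphur pathway (median 0.11), glycolysis (0.18), heat shock (0.13) and nitrogen use (0.042) lay higher on denture material and fatty acid breakdown (-0.10) lower, with adjusted p-values of 4.95e-08, 2.66e-06, 0.0015, 0.00733 and 6.8e-05. Their adjusted p-values were 0.449, 0.429, 0.24, 0.495 and 0.24 with an estimated correlation. Adjusted over the list alone, 1 amino acid synthesis gene and 2 heat shock genes rose and 2 fatty acid breakdown genes fell.

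Between GDH2346 and SC5314 on denture material, the biofilm difference was lower in GDH2346 for ECM17 (-1.02 ± 0.11), HSP78 (-0.79 ± 0.08) and GRP2 (-0.79 ± 0.08) and higher for CHR1 (0.56 ± 0.07), a putative RNA helicase gene. HSP78 and GRP2 each had 1 of 2 probes past the threshold. The replicates of ECM17 were -0.76 and -0.80 in GDH2346 and 0.28 and 0.19 in SC5314. The largest adjusted p was 0.0403 (CHR1). Ribosome biogenesis genes lay higher in GDH2346 as a list (median 0.28, 11 members up adjusted over the list alone) and amino acid synthesis genes (median -0.14, 10 down adjusted over the list alone) and heat shock genes (median -0.26, 6 down adjusted over the list alone) lower. These lists had adjusted p-values of 3.21e-14, 1.59e-07 and 0.000553, with an adjusted p = 0.428, an adjusted p = 0.428 and an adjusted p = 0.366 with an estimated correlation. Of 8 lists that passed camera, the others were ribosomal proteins (median 0.14) and iron and copper uptake (0.065), which lay higher in GDH2346, and glycolysis (-0.19), hexose transporters (-0.080) and secreted proteases and lipases (-0.076), which lay lower, with 0 members past the threshold in each. Their adjusted p-values ranged from 0.0239 to 0.0314, and from 0.428 to 0.798 with an estimated correlation. In all 9 features passed, 3 higher and 6 lower. Counts were 6 higher and 5 lower without centring and 2 lower with arrays scaled to one spread. They were 2 with directly hybridised pairs alone and 0 with unnamed spots included. The count was 1 and 0 without SC5314 denture replicates 1 and 2, 0 without either replicate of SC5314 catheter or of GDH2346 denture, and 91 and 92 without M61 catheter replicates 1 and 2, and limma gave 821 features an unadjusted p under 0.05 over all loops.

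Between M61 and SC5314 on catheter material, the biofilm difference was higher in M61 for RBT1 (1.65 ± 0.17, 1 of 2 probes), the glutathione peroxidase gene GPX2 (0.93 ± 0.07) and ECE1 (0.56 ± 0.07). It was lower for URA2 (-1.83 ± 0.21), ALD5 (-1.47 ± 0.17), HGT17 (-1.39 ± 0.14), CTN1 (-1.32 ± 0.14), ECM17 (-1.03 ± 0.11) and ASR2 (-0.83 ± 0.10). The replicates of RBT1 were 1.56 and 0.97 in M61 and -0.39 and -0.38 in SC5314, and the largest adjusted p among these genes was 0.0289. GPX2 had an adjusted p of 0.117 without SC5314 catheter replicate 1, and CTN1 one of 0.275 without SC5314 catheter replicate 2. Hypha-associated genes lay higher in M61 as a list, with 2 of 22 past the threshold (5 adjusted over the list alone). Camera gave an adjusted p of 5.27e-08, and an adjusted p = 0.0806 with an estimated correlation. Fatty acid breakdown genes lay lower (6 adjusted over the list alone), with ANT1 at -0.57 ± 0.11, which did not pass over all features. Its adjusted p was 0.0015, with an adjusted p = 0.269 with an estimated correlation. Of 5 lists that passed camera, the others were cell wall (median 0.0995), ribosome biogenesis (0.094) and ergosterol synthesis (0.085), which lay higher in M61 with 0 members past the threshold in each. Their adjusted p-values were 0.000117, 0.000276 and 0.00378, with an adjusted p = 0.374, an adjusted p = 0.665 and an adjusted p = 0.374 with an estimated correlation. In all 12 features passed, 5 higher and 7 lower, against 22 without centring (5 higher and 17 lower). There were 2 higher with arrays scaled to one spread, 3 higher with each print block centred and 4 with directly hybridised pairs alone. The count was 3 without either replicate of SC5314 denture, 0 without either replicate of SC5314 catheter, 4 without either replicate of GDH2346 denture, and 62 and 42 without M61 catheter replicates 1 and 2, and limma gave 437 features an unadjusted p under 0.05 over all loops.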

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

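The tests for weak 48 h arrays and for a larger spread, the centring and cross-hybridisation tests and both tests of unnamed probes were chosen after the result was seen. For those on print blocks and turned loops the bounds were written before their values were known, when the changes themselves had been seen. Among values of named genes, 5 of 140 had a loop set apart from the others. Chance flags about 1 in 20 groups (4.9% of simulated sets of 8 normal values), a rate not established for genes picked for one sign in every loop. PGA6, a putative surface protein gene, was at -4.31 in biofilms from 6 to 12 h in SC5314 denture replicate 2 (others -2.71 to -1.42). The glycolysis regulator gene TYE7 was at 2.53 in biofilms from 12 to 48 h in SC5314 catheter replicate 2 (others 0.44 to 1.37) and at 2.47 in the change of the biofilm difference over the same interval (others 0.10 to 0.98). The chaperone gene SIS1 was at 3.33 in biofilms from 12 to 48 h in SC5314 denture replicate 2 (others 0.46 to 0.84). The peroxiredoxin gene PRX1 was at -0.34 in planktonic cells from 12 to 48 h in GDH2346 denture replicate 1 (others -2.03 to -1.30).

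The biofilm difference itself changed from 6 to 12 h for 491 features. It rose for HGT7 (3.07), GUT2 (2.38), ALS9 (2.31), CNT (2.13), ICL1 (2.10) and PTR22 (2.05) and fell for PGA6 (-1.52), MEP2 (-1.30), HSP90 (-1.27), BAT22 (-1.20), ENO1 (-1.10) and PDI1 (-1.04). From 12 to 48 h it changed for 662 features. It rose for RIM101 (1.43), HSP104 (1.30), STB3 (1.00), TYE7 (0.84), MID1 (0.80) and GRP2 (0.73) and fell for RPS6A (-3.11), URA2 (-2.85), RPL18 (-2.68), ECM17 (-2.67), IFH1 (-2.32) and RPL8B (-2.32). Between GDH2346 and SC5314 9 features differed, with CHR1 at 0.56, ECM17 at -1.02, HSP78 at -0.79 and GRP2 at -0.79. Between M61 and SC5314 12 differed, with RBT1 at 1.65, GPX2 at 0.93, ECE1 at 0.56, URA2 at -1.83, ALD5 at -1.47, HGT17 at -1.39, CTN1 at -1.32, ECM17 at -1.03 and ASR2 at -0.83.

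With the sign of some loops turned in 100 ways, the real one among them, only 1 of 100, the real one, gave as many features in each of 10 comparisons. The highest other counts were 199 at 6 h, 335 at 12 h, 85 at 48 h and 610 for the average over times. They were 400 and 463 in biofilms over the earlier and later interval, 142 and 15 in planktonic cells, and 109 and 392 for the change of the biofilm difference. These came from turning both loops of a combination.

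Fewer features differed at 48 h (238) than at 12 h (1108), and CTN1 and CRZ2 were among those that passed at both. Whether weak 48 h arrays in replicate 1 explain the fall cannot be told. Without the weak dye-swap pairs and on 6 equal loops the counts were 321 at 12 h and 400 at 48 h (125%). That also dropped 12 h arrays without weak dye swaps. A version run first gave 1101 and 399 (36.2%), on 8 loops at 12 h against 6 at 48 h. Equal loops were chosen after these values were seen. A larger spread with differences of the same size cannot be told apart, since the covariance between replicates at 48 h was 40.6% of that at 12 h (30.5% to 55.1% with a combination left out), against 80% needed. Without the weak pairs it was 49.5% over the 2 SC5314 combinations, 46.6% on denture and 83.8% on catheter material, and the last value keeps it open.

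Of 40 ribosomal protein genes 31 fell in biofilms from 12 to 48 h, with a list median of -0.99. The list did not pass camera with an estimated correlation. Centring does not account for the fall, as without it the median was -1.22 (-2.61 to -0.53 over 8 loops). Nor does spot position in print blocks, with a median of -0.98 when each block was centred. Cross-hybridisation that makes many probes follow one gene could not be tested by gene names. The 31 genes code for 29 different ribosomal proteins by the number in their names, and different ones are not near-identical. But the 40 genes of the list code for 37, so a high count was fixed once 31 had fallen. Between paralogues of one protein cross-hybridisation was not tested.

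Probes without a gene name were outside the main measurement, and 147, 172 and 98 of 763 tested passed at 6, 12 and 48 h. Among all unnamed probes 127 had differences beyond 4 at every time, 67 higher and 60 lower in biofilms, where the largest averaged difference of a named feature was 1.89. Failed or one-dye spots do not account for them, since such probes, picked on the other loops, had the labelled sign on 96 of 96 arrays. That test replaced an earlier one that could not separate the explanations, and was written when 96 was known. Control RNA added in different amounts to biofilm and planktonic extracts may explain them, with 81.9% of the probes within 1.5 between 6 and 48 h, near the bound of 80% set for it, though their identity is not given.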

How the results depend on the processing

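The cause was not tested for any change below, and the counts are features past the threshold. Without centring, 48 h had 4570, biofilms from 12 to 48 h 1840 and the change of the biofilm difference over that interval 1756. The 6 h count was 491, with planktonic cells from 12 to 48 h 182, GDH2346 392, SC5314 catheter 149, denture against catheter 2 and M61 against SC5314 22. Without centring, values turned for CIC1 (-0.0519), CTA4 (-0.0674) and SFL1 (-0.0704) at 48 h, CLB4 (-0.0211) for the average over times, and ERG13 (-0.0072) and RPS25B (-0.0079) in M61. With arrays scaled to one spread, 48 h had 100, planktonic cells from 12 to 48 h 42, and GDH2346 and M61 against SC5314 2 each, and with print blocks centred M61 against SC5314 had 3. With the replicate block SC5314 catheter had 102, and the average over times 1519 against 1475. With unnamed spots SC5314 catheter had 108 and GDH2346 against SC5314 0.

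Without the weak dye-swap pairs, 48 h had 399, the average over times 909, the change of the biofilm difference from 12 to 48 h 274, SC5314 denture 342, SC5314 catheter 125, GDH2346 228, M61 119, GDH2346 against SC5314 0 and M61 against SC5314 21. With equal loops as well, these were 400, 908, 282, 342, 125, 225, 119, 0 and 21. Further counts were 321 at 12 h, 627 and 495 in biofilms over the earlier and later interval, 222 and 12 in planktonic cells and 193 for the change of the difference from 6 to 12 h. Directly hybridised pairs alone gave 108 in SC5314 denture, 202 in M61, and 2 and 4 for GDH2346 and M61 against SC5314. One mean over the loops gave 40 in planktonic cells from 12 to 48 h and 381 for the change of the difference over that interval.

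Arrays as units gave 1358 at 6 h, 939 at 48 h, 2336 for the average, 1212 in biofilms and 184 in planktonic cells from 12 to 48 h and 1188 for the change of the difference. It gave 1069, 602, 1776 and 1344 in SC5314 denture, SC5314 catheter, GDH2346 and M61. It further gave 24, 674 and 271 between surfaces, for GDH2346 and for M61 against SC5314. In the same order of comparisons as the report, from 6 h to M61 against SC5314 and leaving out the surfaces, the unmoderated t-test gave 190, 114, 2, 694, 572, 223, 101, 0, 26, 92, 0, 1, 31, 19, 0 and 0. Within combinations the order is SC5314 denture, SC5314 catheter, GDH2346, M61. With its Bonferroni threshold it gave 1, 0, 0, 4, 3, 3, 1, 0, 3, 0, 0, 1, 2, 3, 0 and 0, and limma with a Bonferroni threshold 70, 41, 17, 97, 130, 113, 59, 12, 34, 45, 15, 11, 29, 24, 0 and 2.

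Leaving out a loop gave 488 to 1046 at 6 h, 598 to 1177 at 12 h, 35 to 460 at 48 h and 934 to 1682 for the average. It gave 853 to 1035 and 547 to 784 in biofilms, 327 to 481 and 37 to 157 in planktonic cells, and 232 to 528 and 359 to 577 for the change of the difference. Within SC5314 denture, SC5314 catheter, GDH2346 and M61 it gave 8 to 510, 8 to 229, 45 to 1068 and 173 to 556, and between surfaces, for GDH2346 and for M61 against SC5314 0, 0 to 92 and 0 to 62. A lone loop of a combination is then assumed to vary like the others. Of 138 list results 0 stayed past the threshold with an estimated correlation, 122 to 133 with a loop left out and 125 without centring. Counting lists that passed only there, 129 to 155 passed with a loop left out and 171 without centring. Of 510 gene results, 89 lost their call without centring, 65 with scaled arrays, 29 with print blocks, 68 without weak pairs, 128 with equal loops and 14 with the replicate block. The unmoderated t-test ended 318 calls, its Bonferroni threshold 505 and limma at a Bonferroni threshold 349. With a loop left out 39 to 111 lost it (111 and 104 without SC5314 denture replicates 1 and 2), of 504 to 510 with a value, and 86 lost it in at least 4 of the left-out loops. Unnamed spots ended 23 calls, arrays as units 11, no filter 7, one mean over the loops 47 of 403 and directly hybridised pairs 48 of 351.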

Other observations

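Biofilm regulators and drug efflux genes were measured as lists whose camera test did not pass in any comparison. Among 13 biofilm regulators, 3 rose and 1 fell at 12 h (4 and 1 adjusted over the list alone), with the transcription factor genes NDT80 at 1.05 ± 0.14 and FLO8 at 0.45 ± 0.10 and the glycolysis regulator gene TYE7 at -0.71 ± 0.15. The adjusted p was 0.0604, with an adjusted p = 0.573 with an estimated correlation. Among 12 drug efflux genes, 1 rose and 2 fell at 6 h (2 and 2 adjusted over the list alone), with the ABC transporter gene CDR4 at -1.01 ± 0.10 and FLU1 at 0.33 ± 0.05. The efflux list had an adjusted p of 0.699 at 6 h, with an adjusted p = 0.713 with an estimated correlation.

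The covariance between replicates for the average over times was 0.0543 in GDH2346, 0.0302 in M61, 0.0289 in SC5314 denture and 0.0186 in SC5314 catheter, and no explanation for this was tested. Replicates correlated across genes at r = 0.769 at 6 h, 0.846 at 12 h and 0.467 at 48 h. Of the 127 unnamed probes with large differences, 89.8% had another such probe 24 positions away, where the highest of 1000 random sets had 25.2%, a spacing picked from the data.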
